A study of Homo sapiens with 24 samples.

How the data were processed

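RNA was measured by sequencing in HT-144, an established human melanoma cell line derived from a metastatic site. Cells were transfected for 3 days with antisense oligonucleotides (ASOs, single strands that direct cleavage or block a complementary RNA) at 5 nM or with pooled small interfering RNAs (siRNAs) at 50 nM, per the labels' protocols. The 6 groups were a mock transfection, a non-targeting siRNA (siNegative), an siRNA pool for SREBF1 (siSREBF1), a non-targeting ASO (ASO-Neg) and 2 ASOs for SREBF1 (ASO-SREBF1-S1 and ASO-SREBF1-S4). Libraries were strand-specific, made from polyadenylated RNA and sequenced as read pairs of 75 bp, per the labels' protocols.

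The deposited values were whole-number read counts per gene, 1 file per sequencing lane, with columns for unstranded counting and for each strand. The authors aligned reads with STAR 2.6.1a to GRCh38 and used FastQC, per the submitters' processing notes. The annotation behind the 58735 genes in each file was not given in the sources used here. Reads that named no gene stood in 4 summary lines per file and were left out of library sizes and tests. Of all read pairs, 80.65% to 81.82% were assigned to a gene in a library. The reverse-strand column was used throughout, since the other strand held only 6.47% to 7.79% of the counts of both. Of the gene identifiers, 58207 matched GENCODE release 44, and they held 99.93% of the counts. Coordinates are from that release on GRCh38.

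The 24 files were 4 lanes of each of 6 libraries, which the series text calls technical replicates. Lanes of 1 library had a chi-square to degrees of freedom ratio between 1.018 and 1.047 over genes, against 2.03 to 8.69 for lanes of different libraries. Lanes were summed, so each group was 1 library. Summed counts were 12916478 for mock, 20014261 for siNegative, 13206869 for siSREBF1, 17415823 for ASO-Neg, 47900277 for ASO-SREBF1-S1 and 15901894 for ASO-SREBF1-S4. A count of 3 was worth 0.0626 CPM (read counts scaled to library size) in the deepest library and 0.232 CPM in the shallowest. Intervals cover counting error only.

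Tests used edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr, the quasi-likelihood F test (2-sided) and Benjamini-Hochberg adjustment at 0.05. The main comparison set the 3 SREBF1-targeting libraries against the 3 control libraries. Mock, which received no ASO or siRNA, stood only on the control side. Effects of transfecting any such reagent are therefore mixed into that comparison. A fit with 3 classes gave the ASO pair against the controls and siSREBF1 against the ASO pair. A further fit tested chemistry (ASO or siRNA) with the target as a term. The 3 libraries of a side received different reagents, so p-values measure the spread between reagents as well as between cultures. Contrasts of 1 library over 1 library have no p-value. They are log2 ratios of TMM-scaled CPM with a prior count of 2, a 95% counting interval and a size rule of at least 1 on the log2 scale with 10 CPM in 1 of the 2 libraries.

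Before the data were examined, 24 gene lists were fixed: 19 pathway lists, 4 lists of other cell types and 1 of mitochondrially encoded genes. The pathway lists were fatty acid synthesis, cholesterol synthesis, sterol uptake and SREBP control, glycerolipid synthesis and lipid droplets, fatty acid oxidation and PPAR targets, LXR targets, the unfolded protein response, ATF4 targets, interferon response, NF-kB and inflammatory genes, p53 targets, apoptosis regulators, G1/S and replication, G2/M, melanocytic differentiation, dedifferentiated melanoma with YAP/AP-1, hypoxia and glycolysis, NRF2 and oxidative stress, and small RNA and antisense machinery. The lists of other cell types held fibroblast, keratinocyte, immune and endothelial markers. Lists with at least 5 measured members were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry beside it. In single-library contrasts a list's median was placed among the medians of 10000 random lists of the same size matched on mean expression. Random lists do not carry the correlation between members of a real list, so a place outside them is a description and not a test. SOD2, listed under NF-kB, and LOR, a keratinocyte symbol, had no match by symbol, so counts under another identifier, if any, were not in their lists.

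The rule for named genes was also fixed beforehand. It took SREBF1 and SREBF2, the 10 largest rises and falls past the threshold with a mean of at least 5 CPM, the 5 largest rises and falls of each single-library contrast, genes at least 2-fold the same way in all 3 matched SREBF1 contrasts, and up to 4 members per list. The main comparison also required the 2 sides not to overlap. List members were taken first from those past the threshold over all genes and then by the smallest p. Genes without a symbol and sex-linked markers were left out of the rule, and some list members that the rule took are not reported here.

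The tests were run on simulated counts with planted changes. For the main comparison, over 14934 genes, 64% of 1.5-fold changes and 100% of 2-fold, 4-fold and 8-fold changes were recovered, with 12 false calls. For the ASO pair 76% of 1.5-fold changes were recovered, for the difference between siSREBF1 and the ASO pair 40% of 1.5-fold and 88% of 2-fold changes, and for chemistry 68% of 1.5-fold changes. camera called the planted list and 0 of 20 unchanged lists. Genes were drawn independently there, while the estimated correlation within the real lists reached 0.599 (G1/S). That result therefore says nothing about false calls among correlated genes. These simulations used a trended dispersion only, which makes them optimistic for genes that vary more than the trend. The recovery runs planted 50 changed genes at each fold size, which eases the adjusted threshold, while the real main comparison called 9 genes in edgeR. The recovered shares may therefore overstate the power of the tests on these data. The list percentile, over 15123 genes with 20 lists per setting, found 9 of 20 lists moved by 0.2 on the log2 scale, so small list changes can be missed. It found 20 of 20 moved by 0.5, a size added after the result for 0.2 was seen, and placed 2 of 20 unchanged lists outside its limits.

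Sequence scans used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1. Words of 7 bases in 3' UTRs were scored by the mean log2 ratio of the genes carrying them, within bins of 3' UTR length. Bins of GC content were added after that scan was seen. Windows of SREBF1 pre-mRNA were scored likewise within bins of gene length over 10055 genes, at lengths of 13, 11 and 15 bases. Each best score was set against the 95th percentile of 200 shuffles. The plan was to count 13-base windows among fallen genes, which repeats made void. The scans over all genes were chosen afterwards, as were their limits: windows in under 2% of genes, at least 3 carriers, a margin of 0.5 over the shuffles, and a score above -3 in contrasts without the library. On simulated ratios each scan recovered 20 of 20 planted sets, moved by -0.1 for words and -0.5 for windows.

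Alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, limma-voom, no filter on low counts, the unstranded column, chemistry as a term, leaving out each library or lane, lanes as separate columns, another prior count, a 1 CPM limit and mock as control. Thinning ASO-SREBF1-S1, leaving out genes overlapped by an abundant gene on the other strand, and further settings for the gene lists were added after seeing the data. The limit of 0.1 for calling a correlation moved was a choice with no test behind it. The sequences of the reagents were not used here.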

Results

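Polyadenylated RNA of HT-144 melanoma cells was sequenced after transfection with reagents against SREBF1, which encodes a transcription factor of lipid synthesis genes, or with controls. There were 3 SREBF1-targeting libraries (an siRNA pool and 2 ASOs) and 3 control libraries (mock, siNegative and ASO-Neg), 1 per group, with 12916478 to 47900277 gene counts each. By its title, the series was made to study the specific effects of a SREBF1-depleting ASO.

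SREBF1 itself (ENSG00000072310, GRCh38 chromosome 17, 17810399 to 17837002) stood at 231.9 CPM in mock, 249.69 in siNegative and 217.41 in ASO-Neg, and at 55 in siSREBF1, 77.05 in ASO-SREBF1-S1 and 70.41 in ASO-SREBF1-S4. It fell from 233 ± 16.2 CPM in the controls to 67.5 ± 11.3 CPM (SD, n = 3 each), a fold of 0.291. Genes of fatty acid handling fell with it: SCD, the desaturase that makes monounsaturated fatty acids, by 0.90 on the log2 scale, ACSL1, which activates long-chain fatty acids, by 0.63, and FABP7, a fatty acid binding protein, by 1.12. IL21R, a cytokine receptor, fell by 1.70 and PRUNE2 by 0.88. AP3B2, a subunit of a neuronal vesicle adaptor, rose by 0.84.

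**Figure D1:**
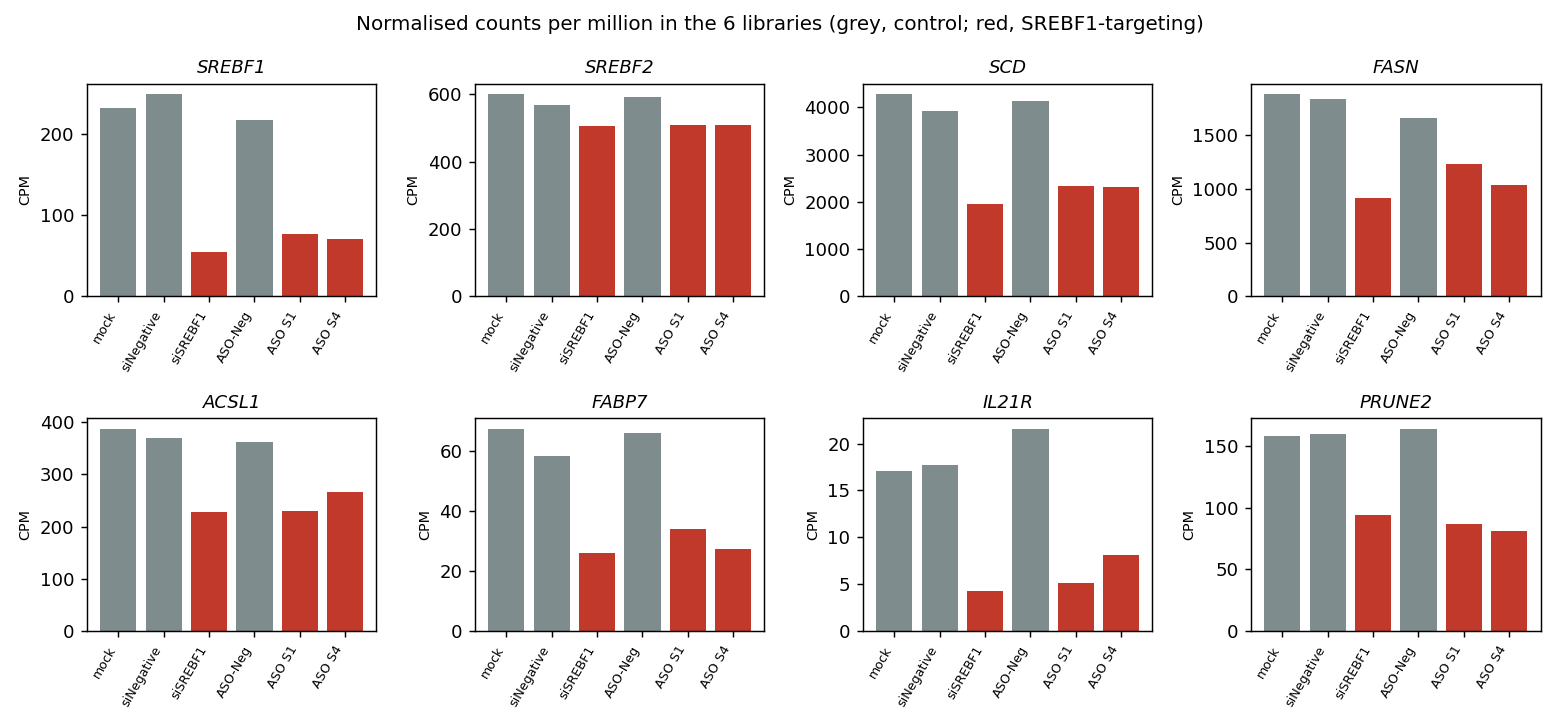
Bars give normalised read counts scaled to library size (CPM) of 8 genes in the 6 libraries, 1 library per bar, with controls in grey and SREBF1-targeting libraries in red. SREBF1, SCD, ACSL1, FABP7, IL21R and PRUNE2 are lower in each targeting library than in each control, with SREBF1 at 55 to 77.05 against 217.41 to 249.69.

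In edgeR's quasi-likelihood test of the 3 SREBF1-targeting against the 3 control libraries, 9 of 15123 genes passed an adjusted p of 0.05, 3 higher and 6 lower. SREBF1 had a log2 ratio of -1.78 (SE 0.12, edgeR adjusted p = 0.00164). SCD went from 4110 ± 185 to 2210 ± 216 CPM (SD, n = 3; log2 ratio -0.90, SE 0.096, edgeR adjusted p = 0.0224). FABP7 went from 63.8 ± 4.89 to 29.1 ± 4.16 CPM (SD, n = 3; edgeR adjusted p = 0.0142), and PRUNE2 from 161 ± 3.09 to 87.2 ± 6.63 CPM (SD, n = 3; edgeR adjusted p = 0.00508). ACSL1, IL21R and AP3B2 each had an edgeR adjusted p of 0.0442. SPRR2D (log2 ratio 1.93) and BIRC3, an inhibitor of apoptosis (1.56), also rose, with means under 5 CPM over the libraries, and are named after their values were seen. SREBF2, which encodes the related factor of cholesterol genes, went from 587 ± 17.3 to 508 ± 2.72 CPM (SD, n = 3; log2 ratio -0.21) and did not pass (edgeR adjusted p = 0.322). At an unadjusted p under 0.05 there were 1546 genes, and the sides did not overlap for 17.4% of genes, where chance gives 10%. With chemistry as a term no gene passed in edgeR (812 at an unadjusted p under 0.05), without mock or ASO-Neg only SREBF1 did and without siNegative 3 genes. Without ASO-SREBF1-S1 the count was 103, while the DESeq2 Wald test called 165 and limma-voom 5. The p-values measure only the spread between these libraries, which received different reagents.

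The fatty acid synthesis list was lower in the targeting libraries. Of 23 measured members, 14 fell and 0 rose adjusted over the list alone in edgeR, and 2 fell over all genes. Besides SCD and ACSL1, FASN, the fatty acid synthase, went from 1800 ± 117 to 1060 ± 160 CPM (SD, n = 3) and ACACA, which makes malonyl-CoA, from 269 ± 21.2 to 203 ± 4.19 CPM (SD, n = 3). The list's median log2 ratio was -0.29 (camera adjusted p = 1.78e-22, and adjusted p = 0.0129 with an estimated correlation). It was the 1 of 11 called pathway lists, out of 19, whose call held with an estimated correlation. In fry, 3 lists passed: fatty acid synthesis (adjusted p = 0.00393), sterol uptake (0.0185) and apoptosis regulators (0.0424).

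The cholesterol synthesis list showed no common direction. Of 22 members, 3 rose and 2 fell adjusted over the list alone: TM7SF2, NSDHL and SC5D were higher (log2 ratios 0.69, 0.29 and 0.26), and FDPS and LSS lower (-0.33 and -0.27). Its median log2 ratio was -0.06 (camera adjusted p = 0.58). The sterol uptake and SREBP control list was lower, with 4 of 15 members falling adjusted over the list alone, among them LPIN1 (-0.54), INSIG1 (-0.66) and CYB5R3 (-0.28). Its camera adjusted p was 0.000289, with an adjusted p = 0.13 with an estimated correlation. Its 4 became 2 without siNegative, ASO-Neg or ASO-SREBF1-S1, and the cholesterol genes went from 3 higher and 2 lower to 1 higher and 0 lower without siNegative, 1 and 1 without mock, 4 and 5 without ASO-SREBF1-S1, and 0 and 0 with chemistry as a term.

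**Figure D2:**
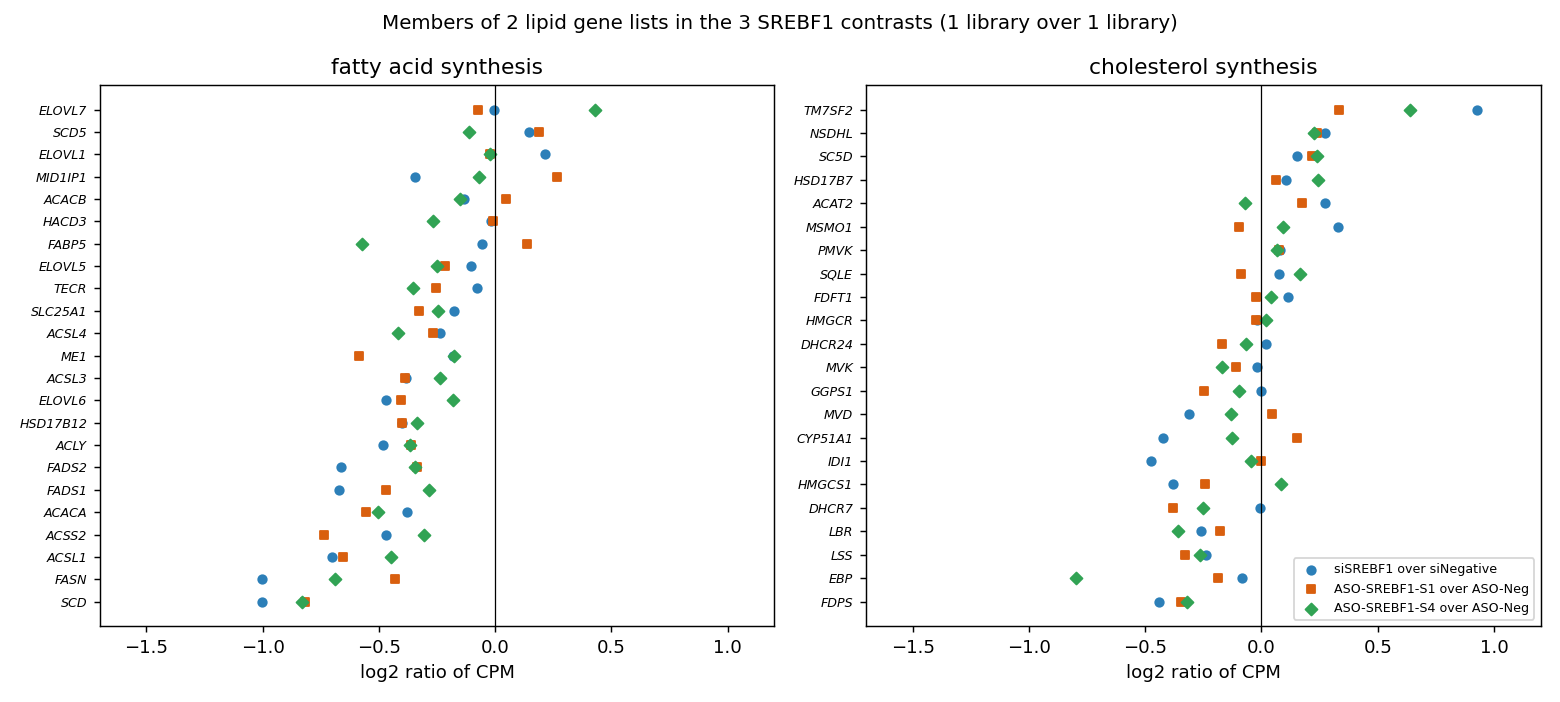
Points give log2 ratios of CPM for members of the fatty acid synthesis list (left) and the cholesterol synthesis list (right) in the 3 SREBF1 contrasts, each 1 library over its matched control. SCD lies at -0.82 with ASO-SREBF1-S1 and -0.83 with ASO-SREBF1-S4, and TM7SF2 lies at 0.93, 0.33 and 0.64.

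Among other lipid lists, PCYT2, an enzyme of phosphatidylethanolamine synthesis, fell (log2 ratio -0.38), the 1 of 22 glycerolipid members to pass adjusted over the list alone. That list's median was 0.04 while camera's direction was down (adjusted p = 0.845). HADHA, of mitochondrial fatty acid oxidation, was the 1 of 23 members of its list to fall over the list alone (-0.44; camera adjusted p = 0.119). ABCA1, a cholesterol exporter, was the 1 of 7 LXR targets to rise over the list alone (0.95; camera adjusted p = 0.319). In the NRF2 list, 2 of 21 members fell adjusted over the list alone, among them PGD (-0.58) (camera adjusted p = 0.00125, adjusted p = 0.386 with an estimated correlation). They became 4 without ASO-SREBF1-S1 and 1 without mock, siNegative, siSREBF1 or ASO-Neg. No fatty acid oxidation gene passed without mock, siNegative or ASO-Neg, while 2 fell over the list alone without ASO-SREBF1-S1. For that list camera made a call without siNegative (adjusted p = 0.0397) or siSREBF1 (0.0487). Of LXR targets, 2 rose over the list alone without ASO-SREBF1-S1, and 1 rose and 1 fell without ASO-SREBF1-S4.

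Inflammatory genes were higher in the targeting libraries. In the NF-kB list 9 of 18 members rose adjusted over the list alone, 1 of them over all genes: BIRC3, the chemokines CXCL8 (log2 ratio 1.67) and CXCL1 (1.09), and IRF1 (0.51) were among them. The list's median was 0.47 (camera adjusted p = 5.11e-14, adjusted p = 0.13 with an estimated correlation). CXCL8 stood at 30.2 ± 16.5 CPM against 9.16 ± 1.83 in the controls (SD, n = 3). Of 25 p53 targets, 5 rose and 1 fell adjusted over the list alone, with TP53I3 at 0.72, AEN at 0.30, XPC at 0.37 and MDM2, the p53 ubiquitin ligase, at 0.44 (camera adjusted p = 3.22e-08, adjusted p = 0.361 with an estimated correlation). Of 26 dedifferentiation and YAP/AP-1 genes, 6 rose and 1 fell adjusted over the list alone, with FN1 at 0.43, CCN1 at 1.05 and JUN at 0.76 (camera adjusted p = 0.00073, adjusted p = 0.198 with an estimated correlation). These counts changed with the libraries and terms used. The 9 NF-kB genes became 5 without siNegative and 4 without ASO-Neg, while the list's median was 0.48 and 0.45. The 6 dedifferentiation genes became 0 without mock, without siNegative or with chemistry as a term, with medians of 0.11, 0.15 and 0.08 (0.11 in the main fit). Without mock the dedifferentiation list had a camera adjusted p of 0.0359. Leaving out a library also lowered the residual degrees of freedom from 4 to 3. The 5 rising p53 targets became 0 without mock, without ASO-Neg or with chemistry as a term, 3 without siNegative, 9 without siSREBF1 and 10 without ASO-SREBF1-S1. Their list's median was 0.22 in the main fit, without mock 0.22, without ASO-Neg 0.21 and with chemistry as a term 0.21.

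Of 24 ATF4 targets, CEBPG (log2 ratio 0.42) and SESN2 (0.61) rose adjusted over the list alone (camera adjusted p = 0.00073, adjusted p = 0.494 with an estimated correlation). Without ASO-SREBF1-S1 that list was not called (median -0.003, camera adjusted p = 0.686), and the 2 genes became 0 without mock, siNegative or ASO-SREBF1-S1 and 4 without siSREBF1. No member passed over its list alone in edgeR for the unfolded protein response (camera up, adjusted p = 0.0186, adjusted p = 0.494 with an estimated correlation) or the interferon response (camera up, adjusted p = 0.0179, adjusted p = 0.625 with an estimated correlation). The interferon list turned down without ASO-SREBF1-S1 (median -0.006, camera adjusted p = 0.708) and was not called without siNegative (0.0725) or with chemistry as a term (0.0562). The unfolded protein response was not called without mock (camera adjusted p = 0.25), without ASO-SREBF1-S4 (0.367) or with chemistry as a term (0.216). No G2/M gene passed over its list alone either, and 24 of 25 had a log2 ratio below 0, among them KIF20A (-0.33) and MKI67 (-0.30) (camera adjusted p = 1.34e-06, adjusted p = 0.46 with an estimated correlation). No melanocytic gene of 25 passed over its list alone (median -0.15, camera adjusted p = 0.000248, adjusted p = 0.43 with an estimated correlation). Without mock the melanocytic median was -0.10 (camera adjusted p = 0.0346). Without ASO-SREBF1-S1, 12 G2/M genes and 6 melanocytic genes fell adjusted over the list alone. Among apoptosis regulators MCL1 (0.42) and PMAIP1 (0.39) rose and BCL2 (-0.66) fell adjusted over the list alone (camera adjusted p = 0.319), and none passed without mock, siNegative, siSREBF1, ASO-Neg or ASO-SREBF1-S4. The G1/S, hypoxia and glycolysis, and small RNA machinery lists had no member past the threshold over the list alone and camera adjusted p values of 0.537, 0.93 and 0.319. Without ASO-SREBF1-S1 the G1/S list was called down (camera adjusted p = 0.0123), and without ASO-SREBF1-S4 its direction was up (0.07). The hypoxia and glycolysis median was 0.01 while camera's direction was down. The 13 mitochondrially encoded genes had a median of -0.11 with none past the threshold. Of other cell types, 8 fibroblast markers had a median of 0.17 with none past the threshold, KRT17 was the 1 of 3 measured keratinocyte markers lower over the list alone (0.235 against 0.816 CPM, near the floor), 2 endothelial markers did not pass and no immune marker was measured.

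The ASO pair against the controls asks what SREBF1 ASOs do without the siRNA. SREBF1 fell by 1.66 on the log2 scale (edgeR adjusted p = 0.000578). The adhesion genes CDH13 and NCAM1 fell by 1.48 and 0.93, FABP7 by 1.05, PRUNE2 by 0.94, SGCD, a sarcoglycan, by 0.84 and SCD by 0.82. These 7 of 16297 genes passed in edgeR's quasi-likelihood test, each lower, with adjusted p values from 0.000578 to 0.0322, and 1826 genes had an unadjusted p under 0.05. SREBF2 had a log2 ratio of -0.21 (edgeR adjusted p = 0.373). Among ASO libraries alone no gene passed in edgeR (283 at an unadjusted p under 0.05), and leaving out mock, siNegative or ASO-Neg left SREBF1 alone. Leaving out either SREBF1 ASO left 1 library in that class, so the spread came from the controls alone and the count is not interpreted.

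Set against the ASO pair, siSREBF1 had higher SCG2, a secretogranin (46.05 CPM against 6.68 and 6.65; log2 ratio 2.79), and higher CSMD2 (2.01), EDN3, an endothelin (1.97), CDH13 (1.91) and HAS3, a hyaluronan synthase (1.62). It had lower ATP6V1D, a subunit of the vacuolar proton pump (21.27 CPM against 77.28 and 75.33, log2 ratio -1.85), ANTXR1 (-1.15), HLA-DMA (-1.08), MTPN (-1.06) and NCR3LG1 (-1.06). SCG2, EDN3 and HAS3 were also higher in siSREBF1 than in siNegative (46.05 against 9.62, 15 against 7.45 and 34.56 against 12.61 CPM). CDH13 and CSMD2 differed less there (61.57 against 56.02 and 15.23 against 12.05 CPM). Both were lower in the SREBF1 ASOs than in ASO-Neg (CDH13 15.41 and 17.54 against 38.56 CPM, CSMD2 3.59 and 4.06 against 8.65). In edgeR's test of the difference 24 of 16297 genes passed, 9 higher and 15 lower in siSREBF1, with SCG2 at an adjusted p = 2e-04 and ATP6V1D at 0.000908. SREBF1 was lower in siSREBF1 but did not pass (log2 ratio -0.43, SE 0.123, edgeR adjusted p = 0.324). SREBF2 did not pass (-0.02, edgeR adjusted p = 0.988). siSREBF1 is 1 library and is assumed to vary like the others. The interaction of chemistry and target called no gene in edgeR (201 at an unadjusted p under 0.05). Without mock or ASO-Neg 2 genes passed and without siNegative 3. Without ASO-SREBF1-S1 or ASO-SREBF1-S4 each side was 1 library and the spread came from the controls alone, so the count is not interpreted.

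For ASO against siRNA chemistry, adjusted for the target, no gene passed in edgeR, and no other tool was run. At an unadjusted p under 0.05 there were 588 genes, or 3.89%, fewer than that threshold passes by chance. The smallest p values belonged to LRRC15 (log2 ratio 1.49, edgeR adjusted p = 0.998), NELL1 (-0.77), ADAM19 (-0.62), COL15A1 (-0.51) and CDH13 (-1.33), none of which passed. SREBF1 (0.14) and SREBF2 (0.03) had an edgeR adjusted p of 1. Dose differed with chemistry (5 nM and 50 nM).

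In siSREBF1 over siNegative, SREBF1 was at 22.1% of its control (log2 ratio -2.18, 95% counting interval -2.30 to -2.07) and SREBF2 at 88.9%. IL21R (-2.03), ATP6V1D (-1.64), SGCD (-1.58) and ADAMTS3 (-1.34) were the next lowest. The collagenase MMP1 (2.32), SCG2 (2.25), CXCL8 (2.12), CXCL1 (1.82) and SIRPB1 (1.78) were the highest. With 1 library per side there is no replicate check: 30 genes were at least 2-fold higher and 21 lower. The NF-kB list (median 0.63) and the hypoxia and glycolysis list (0.15) lay above all matched random lists, a measure that also placed 2 of 20 unchanged simulated lists outside its limits. The hypoxia and glycolysis list was lower in siNegative over mock (median -0.08, percentile 0.07). In siSREBF1 over siNegative the 13 mitochondrially encoded genes were all lower (median -0.20, percentile 0.11).

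In ASO-SREBF1-S1 over ASO-Neg, SREBF1 was at 35.5% (log2 ratio -1.495, 95% counting interval -1.56 to -1.43) and SREBF2 at 86.1%. SPIRE1, an actin nucleator, was lower at 7.53 against 58.2 CPM (-2.93), followed by the deubiquitinase USP9X (-2.34), NUP50-DT (-2.13), IL21R (-2.05) and ANKRD44 (-2.01). DKK1, a secreted Wnt inhibitor, was highest (3.10), followed by FAM219A (2.18), CLDN1 (1.62), SPTBN5 (1.43) and THBS1 (1.22). At least 2-fold, 15 genes were higher and 32 lower. The interferon list (median 0.31), the ATF4 list (0.25) and the p53 list (0.23) lay above all matched random lists, while 12 of 13 mitochondrially encoded genes were lower (median -0.21, percentile 0.25).

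In ASO-SREBF1-S4 over ASO-Neg, SREBF1 was at 32.4% (log2 ratio -1.63, 95% counting interval -1.72 to -1.53) and SREBF2 at 86.1%. COL8A1, a collagen gene, was lowest (-2.23), followed by ZC3HC1 (-2.06), DNAJC6 (-2.03), SREBF1 and DHRS2 (-1.57). FAM219A (2.42), BCAN-AS1 (2.11), the tight junction gene CLDN4 (1.93), TRAF1 (1.85) and CPE (1.67) were the highest. At least 2-fold, 42 genes were higher and 27 lower. The p53 list (median 0.38) and the unfolded protein response (0.23) lay above all matched random lists, and the G2/M (-0.28) and G1/S (-0.26) lists below them. The G2/M list was higher in ASO-Neg over mock, with a median of 0.12 and 23 of 25 members higher. In ASO-SREBF1-S4 over ASO-Neg the 13 mitochondrially encoded genes were all higher (median 0.09, percentile 99.9) and 8 fibroblast markers had a median of 0.47 (percentile 99.83), 5 of them higher. FAM219A stood at 2.77 CPM in ASO-Neg and at 15.3 in mock, so with mock as control its log2 ratios were -0.25 for ASO-SREBF1-S1 and -0.01 for ASO-SREBF1-S4.

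**Figure D3:**
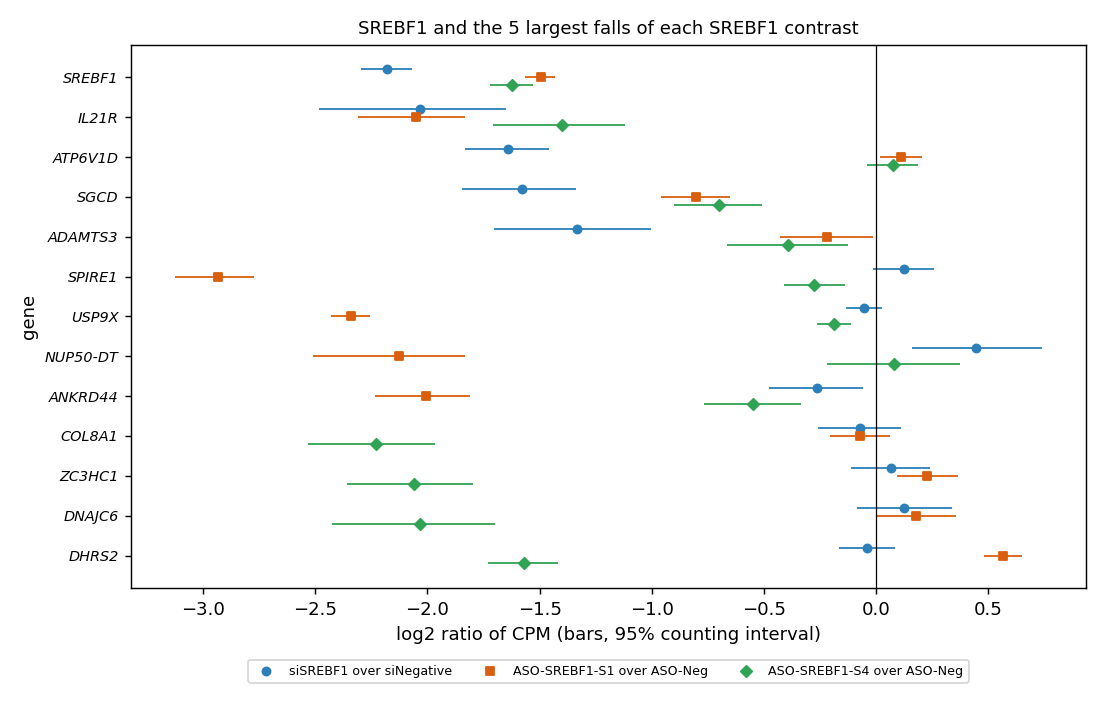
Points give log2 ratios of CPM with 95% counting intervals for SREBF1 and the 5 lowest genes of each SREBF1 contrast, 1 library over 1 library. SREBF1 and IL21R lie below -1 in each contrast, while SPIRE1 lies at -2.93 with ASO-SREBF1-S1 and COL8A1 at -2.23 with ASO-SREBF1-S4.

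Among 10080 genes with 10 CPM in at least 1 library, those at least 2-fold the same way in all 3 matched contrasts were SREBF1, IL21R (-2.03, -2.05 and -1.40) and DKK1 (1.51, 3.10 and 1.86). DKK1 reached 10 CPM only in ASO-SREBF1-S1 and stood at 2.91 CPM in siSREBF1 and 6.65 CPM in ASO-SREBF1-S4. The fatty acid synthesis list had medians of -0.34, -0.34 and -0.28 in the siSREBF1, ASO-SREBF1-S1 and ASO-SREBF1-S4 contrasts, each below all 10000 matched random lists. The NF-kB list had medians of 0.63, 0.34 and 0.34, with percentiles of 100, 100 and 99.98. The cholesterol synthesis medians lay at percentiles of 69.79, 22.33 and 63.13.

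Across 10080 genes, which are not independent replicates, log2 ratios of siSREBF1 correlated with those of ASO-SREBF1-S1 at r = 0.198 (rho 0.182) and with those of ASO-SREBF1-S4 at r = 0.28 (rho 0.226), with no shared control. The ASO contrasts share ASO-Neg and correlated at r = 0.296 (rho 0.295). Unchanged libraries simulated against that control gave r = 0.514 and a covariance of 0.0259, against an observed covariance of 0.0178. The simulated spread includes differences between reagents, so it overstates noise. With no shared control, siSREBF1 and ASO-SREBF1-S4 shared 8 genes at least 2-fold higher, where n1 × n2 / N gives 0.153, and 3 lower (0.0611), and siSREBF1 and ASO-SREBF1-S1 shared 2 higher (0.0521) and 4 lower (0.0764). The ASO contrasts shared 3 higher (0.0655) and 4 lower (0.0972). Each of these counts of shared lower genes includes SREBF1, the target of every reagent, so part of the overlap was fixed by the design, and each includes IL21R. Of the 3 higher in both ASO contrasts, FAM219A and ENSG00000269968 were low in the shared ASO-Neg library, ENSG00000269968 at 10.1 CPM against 36.9 in mock. Counts of ENSG00000269968 were 0.425 times the level that wrong-strand reads of the gene opposite would give, so it is no evidence of a shared rise; it was named after its values were seen. For the ASO pair that product takes the contrasts as independent, which a shared control makes them not.

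The non-targeting reagents are compared with mock, 1 library each, so differences between cultures and libraries are included. Against mock, siNegative had lower pigment genes DCT (1040 to 668 CPM, log2 ratio -0.63) and TYRP1 (-0.62), with VEPH1 (-0.75), SERPINF1 (-0.71) and METRNL (-0.63), and higher CHRDL1 (1.02), CXCL14 (0.93), GPC3, TNFRSF11B (0.88 each) and AIM2 (0.79). ASO-Neg had lower FAM219A (-2.43), TUBA1B-AS1 (-1.41), SH3BP5-AS1 (-1.33), GPS2 (-1.17) and KIF13B (-1.10) counts, and higher LRRC15 (1.56), CXCL14 (0.89), SLITRK6 (0.79), PODXL (0.78) and FLRT3 (0.75). Over the 6 libraries, counts of TUBA1B-AS1, SH3BP5-AS1 and GPS2 were 0.451, 1.1 and 1.82 times the level that wrong-strand reads of the gene opposite would give, so these are not given as falls of the genes. The melanocytic list was lower in both, with medians of -0.30 and -0.22, below all matched random lists. The dedifferentiation list was higher, with medians of 0.19 and 0.20, above all of them. The unfolded protein response list was also higher (0.13 and 0.11). The main comparison gave these lists the same directions with mock among its controls, so its calls for them may hold effects of transfection. Across 9679 genes, which are not independent replicates, log2 ratios correlated with the GC content of 3' UTRs at Spearman rho = -0.355 in ASO-Neg over mock, -0.202 in siSREBF1 over siNegative and -0.086 in siNegative over mock, and the random lists were matched on expression only. SREBF1 was at 108% of mock in siNegative and 93.8% in ASO-Neg, and SREBF2 at 94.4% and 98.4%. By the size rule, 1 gene differed in siNegative and 9 in ASO-Neg. In the unstranded column these counts were 0 and 5.

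Between the ASOs, ASO-SREBF1-S1 had lower SPIRE1 (-2.66), CLDN4 (-2.29), NUP50-DT (-2.21), USP9X (-2.15) and BCAN-AS1 (-1.99) than ASO-SREBF1-S4, and higher ZC3HC1 (2.29), DNAJC6 (2.21), COL8A1 (2.16), DHRS2 (2.14) and NPL (1.59). SREBF1 was at 109% and SREBF2 at 100%. At least 2-fold, 30 genes were higher and 77 lower. The ATF4 list (median 0.42), the interferon list (0.38), the melanocytic list (0.31) and the G1/S list (0.27) lay above all matched random lists, and the mitochondrially encoded genes (-0.34) and the dedifferentiation list (-0.27) below them.

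**Figure D4:**
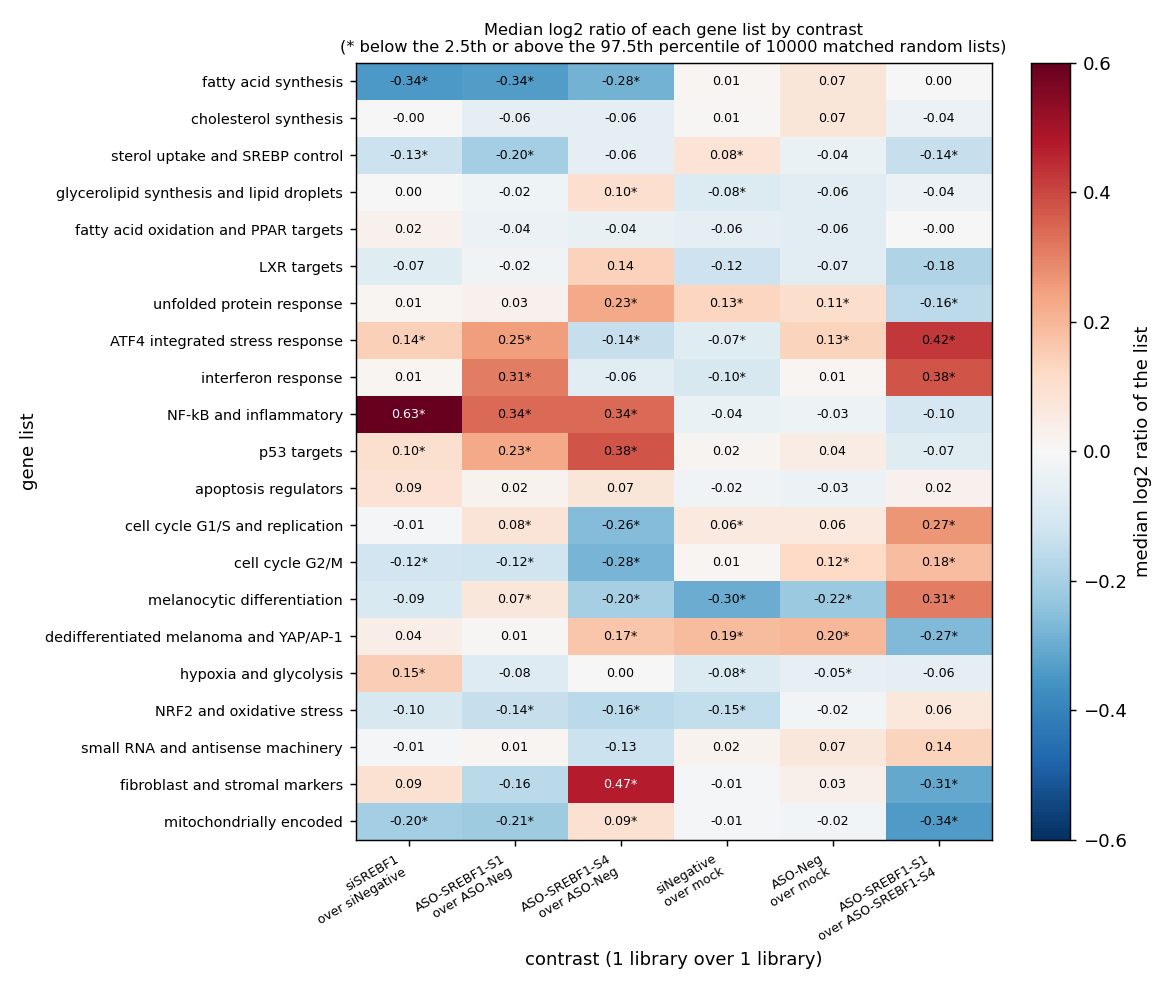
Colours and numbers give the median log2 ratio of each gene list (vertical axis) in 6 contrasts of 1 library over 1 library (horizontal axis), with stars where it lay outside the central 95% of 10000 matched random lists. Fatty acid synthesis lies at -0.34, -0.34 and -0.28 in the SREBF1 contrasts and at 0.01 and 0.07 in the control contrasts.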

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

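The tests of shared effects, antisense transcripts, FAM219A, GC-held words and windows over all genes, with their limits, were chosen after the results were seen, while the splits, length-held words and windows among fallen genes were planned.

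A difference between groups was the reason to look again at the 24 genes that differed between siSREBF1 and the ASO pair in edgeR's test. Higher in siSREBF1, by log2 ratio, were SCG2 (2.79), CSMD2 (2.01), EDN3 (1.97), CDH13 (1.91), HAS3 (1.62), NRP1 (0.95), RPL23AP82 (0.95) and ABHD17C (0.82). Lower were ATP6V1D (-1.85), ANTXR1 (-1.15), HLA-DMA (-1.08), MTPN (-1.06), NCR3LG1 (-1.06), LEPROTL1 (-1.03), ZDHHC5 (-1.02), TTC7B (-0.99), MEF2C (-0.98) and FBH1 (-0.98). The rest of the 24, outside the rule for named genes, were ENSG00000112096, which had no symbol here, MARCHF7, PACSIN2, TMEM123, UHMK1 and VTA1. RPL23AP82 is a pseudogene, so reads shared with related genes are possible and were not tested, and in the unstranded column it did not pass. Outside the gene counts, unmapped read pairs were 3.92% in ASO-SREBF1-S1 and 4.26% in ASO-SREBF1-S4, above the 3.25% of the highest control.

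The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05; the 1 real split called 9 genes and the highest other 0 in edgeR, with up to 1208 at an unadjusted p under 0.05 against 1546.

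Genes at least 2-fold lower with 1 ASO mostly did not follow in the other reagents. For 31 such genes of ASO-SREBF1-S1 the median over the other contrasts was -0.12 (95% bootstrap interval -0.20 to -0.05). For 26 of ASO-SREBF1-S4 it was -0.07 (-0.15 to 0.05). Both were short of the bounds of -0.60 and -0.62, 0.5 of their own medians, which argues against a shared consequence of lower SREBF1 of that size. The genes were chosen by their fall in their own contrast, which enlarges the bounds, and the ASO contrasts share ASO-Neg. A smaller shared fall is not argued against, since the ASO-SREBF1-S1 interval excludes 0. Direct action on transcripts sharing sequence with SREBF1 is a candidate explanation, as a hypothesis: at 13 bases TCTGCTGTCTTGC (chromosome 17, 17818353 to 17818365, coding exon 6) scored -15.37 for ASO-SREBF1-S1 (shuffles -9.05) over 25 carriers with a median of -0.60, 8 of them among the fallen genes, SPIRE1 and USP9X included, and for ASO-SREBF1-S4 GATCTTGACCCTA scored -7.48 (-6.40) over 4 carriers while the 11-base GATCTTGACCC (17812444 to 17812454, exon 19, UTR) scored -11.07 (-5.01) over 99 carriers. It stays open because 3 lengths were tried, the ASO-SREBF1-S1 scores at 11 bases (-6.92, shuffles -6.53) and 15 bases (-9.49, -9.39) were marginal, the latter on the other side of its limit in an earlier run with fewer shuffles, ASO-SREBF1-S4 at 15 bases fell short (-4.85, -6.83), and ASO-Neg over mock also passed its shuffles at 11 bases (-7.60, -6.12). The planned count among fallen genes, 31 and 26, was void because repeats put a shared window in each of them, and with windows in under 2% of genes the highest counts were 8 for ASO-SREBF1-S1 (95th percentile of random sets 7) and 4 for ASO-SREBF1-S4 (6), so that count gave ASO-SREBF1-S4 no excess.

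Genes lower with siSREBF1 followed in part in the ASO contrasts, with a median of -0.44 over 20 genes (95% bootstrap interval -0.76 to -0.18). The bound was -0.58, so a shared fall of that size was not decided, and choosing genes by their own fall enlarges the bound. Medians were -0.53 (-0.83 to -0.12) with ASO-SREBF1-S1 and -0.36 (-0.72 to -0.18) with ASO-SREBF1-S4. These intervals are wholly negative, which argues against effects of the siRNA alone for the 20 genes as a set. Single genes differed, with 9 and 6 of the 20 above -0.25, and both ASO contrasts share ASO-Neg. In the planned scan of 3' UTRs the word CCTATCA scored -7.93 (shuffles -4.43), but ASO-Neg over mock reached -14.38 with a GC-rich word, so that scan did not decide. With GC content held it scored -8.44 (shuffles -4.37) and the next contrast, siNegative over mock, -5.14 (-4.19). A small effect of siRNA seeds stays open as a hypothesis: the word occurs in SREBF1 coding exon 5 (17819165 to 17819171), and the median was -0.043 in 635 genes with it against -0.002 without it. The genes with the word were also lower with ASO-SREBF1-S1 (-0.015 against 0.011), which holds no siRNA, though not with ASO-SREBF1-S4 (-0.021 against -0.023). But they were higher in ASO-Neg over mock (0.047 against 0.011), so the ASO-SREBF1-S1 value may come from its control and does not decide. In siNegative over mock they were higher too (0.015 against -0.002), so part of the siSREBF1 gap may come from its control.

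Antisense transcripts opposite abundant genes were low in ASO-Neg. Wrong-strand reads, measured at 4083 genes with no partner, were 1.21% of right-strand reads in ASO-Neg and 2.61% in mock (log2 ratio -1.10). The 42 transcripts near that floor had a median of -1.32 (95% bootstrap interval -1.40 to -1.19), an interval that leaves out -1.10. TUBA1B-AS1, SH3BP5-AS1 and GPS2 lay within 2 times that floor. The 42 were chosen for counts close to the wrong-strand level, so following it was largely built in. Fewer wrong-strand reads may account for much of their fall. Transcripts well above the floor opposite abundant genes had a median of -0.10 (389 genes, 95% bootstrap interval -0.13 to -0.07), a set chosen after it and the wider set of 7569 genes (-0.009) were seen, which argues against fewer antisense transcripts being made as the whole cause. FAM219A lies far above that floor, and its high ratios in both SREBF1 ASO contrasts are consistent with a change in the shared ASO-Neg library, which was -2.50 from the mean of mock and siNegative.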

How the results depend on the processing

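Thinning ASO-SREBF1-S1, the genes without overlap and further settings for lists were chosen after the data were seen, and the other settings were planned. SREBF1 remained past the threshold of the main comparison in each setting but the chemistry term, which called 0. Its log2 ratio stayed between -1.89 and -1.66 in all of them, while the chemistry term left 2 residual degrees of freedom (4 in the main comparison). The 9 genes were kept with DESeq2 size factors (9) and among those of the unstranded column (10), thinning (10), the DESeq2 Wald test (165), no filter (509) and without ASO-SREBF1-S1, while limma-voom called 5. Leaving out 1 library gave 1 (mock or ASO-Neg) to 103 (ASO-SREBF1-S1), with 3 without siNegative, and leaving out 1 lane of each library gave 4 to 12. Lanes taken as separate columns gave 2746 genes, and 2470 with a replicate block; lanes are technical, so these take counting noise for replicate spread. Without a filter the ASO pair gave 563 (from 7), the difference 380 (from 24) and chemistry 127 (from 0). There the prior degrees of freedom became infinite (5.11 in the main comparison), and other splits called 27 to 381 against 509. The ASO pair gave 0 in ASO libraries only and 1 to 955 leaving out 1 library, the difference 0 as an interaction and 2 to 890, and chemistry 0 to 4, the latter without ASO-SREBF1-S1. For the ASO pair and the difference, the high ends of these ranges came from leaving out an SREBF1 ASO. That left 1 library in the ASO class and the spread came from the controls alone, so those counts are not interpreted. Leaving out a control gave 1 for the ASO pair and 2 or 3 for the difference. Gene lists went from 11 to 1 with an estimated correlation and 3 in fry. A 1 CPM limit gave 294 genes for siSREBF1 over siNegative (from 51), 167 for ASO-SREBF1-S1 over ASO-Neg (from 47), 435 for ASO-SREBF1-S4 over ASO-Neg (from 69), 119 for siNegative over mock (from 1), 203 for ASO-Neg over mock (from 9) and 395 for ASO-SREBF1-S1 over ASO-SREBF1-S4 (from 107), and moved the correlation of the ASO contrasts to 0.415; mock as control of ASO-SREBF1-S4 gave 0.113 and siNegative 0.262. The unstranded column gave 0 for siNegative over mock and 5 for ASO-Neg over mock, and leaving out overlapped genes gave 4. FAM219A reversed with mock as control (-0.252 and -0.009). Of 508 values of named genes in edgeR settings 344 stayed on their side, 152 became weaker, 10 stronger and 2 moved; of 605 in single-library contrasts 587 stayed and 16 moved. The cause was not tested unless stated. At 3 libraries a side, the simulated test recovered 64% of 1.5-fold changes, with a dispersion and a number of changed genes that make it optimistic.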

Other observations

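The tests of gene lists on the ASO pair and on the difference between siSREBF1 and the ASO pair, and the look at genes beside SREBF1, were chosen outside the plan. RAI1, which overlaps the end of SREBF1 on the other strand, had log2 ratios of -0.23, 0.07 and -0.20 in the siSREBF1, ASO-SREBF1-S1 and ASO-SREBF1-S4 contrasts, and the neighbour TOM1L2 had -0.06, -0.13 and 0.04. Of 25 melanocytic genes, 18 were higher and 7 lower in ASO-SREBF1-S1 than in ASO-SREBF1-S4, 1 library each. TYRP1 had a log2 ratio of 0.59 with ASO-SREBF1-S1 and -0.62 with ASO-SREBF1-S4 over ASO-Neg, and DCT had 0.24 and -0.52, while MC1R had -0.12 and 0.31. Of G2/M genes, 25 of 25 were lower with ASO-SREBF1-S4 over ASO-Neg, while 23 of 25 were higher in ASO-Neg over mock.

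In the ASO pair against the controls, 15 of 23 fatty acid synthesis genes fell adjusted over the list alone in edgeR (camera adjusted p = 3.79e-17, adjusted p = 0.0736 with an estimated correlation). siSREBF1 is 1 library, assumed to vary like the others, and the interaction of chemistry and target, the matched form of its difference from the ASO pair, called 0 genes in edgeR (201 at an unadjusted p under 0.05). Between siSREBF1 and the ASO pair, 9 of 20 NF-kB genes were higher in siSREBF1 adjusted over the list alone (camera adjusted p = 3.86e-08, adjusted p = 0.232 with an estimated correlation), as were 7 of 25 hypoxia and glycolysis genes (camera adjusted p = 1.63e-06, adjusted p = 0.436 with an estimated correlation). In that test 2 of 25 p53 targets were lower over the list alone (camera adjusted p = 7.1e-07, adjusted p = 0.232 with an estimated correlation), and interferon genes were lower with none past the threshold (camera adjusted p = 0.000218, adjusted p = 0.971 with an estimated correlation).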
